A study of Homo sapiens with 60 samples.

How the data were processed

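RNA of HepG2 cells, an established hepatocellular carcinoma line, was measured 24 h after treatment with 70% ethanol extracts of 4 herbs and 4 decoctions at 3 doses each, and after vehicle. Per the labels, vehicle was 0.1% DMSO, while the design text names 2% DMSO; the data do not settle which was used. The doses were the concentration giving 20% inhibition, or 500 ug/mL, and dilutions of 5 and 25 times. Hot-water extracts and the wortmannin control were not analysed here. Per the design text, libraries with too little RNA were left out by the authors and RNA integrity numbers were above 7. Groups were read from the labels: 25 groups of 1 to 3 libraries, in sets numbered 11 to 14 with 2 extracts each. Vehicle has its own set label.

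Per the authors, libraries were made with a directional RNA kit and read as 100 bp pairs. Reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to GRCh38 with STAR 2.7.3a and counted with RSEM 1.3.3. The deposited values are expected counts of RSEM per gene, not normalized, and 10.0% of them were not whole numbers, so they were rounded. The annotation release and the strand setting are not given in the sources used here. Of 60675 gene IDs 35976 had a count in at least 1 library. GENCODE 29, which holds 57055 of the IDs, gave symbols and coordinates, and IDs outside it held 0.046% of counts. All columns were used.

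Depth had a median of 23.7 M counts per library. Mitochondrially encoded genes held 8.0% to 19.1% of counts and the 10 most abundant genes 9.3% to 19.7%. Summed markers of other cell types were 635 to 1662 CPM for blood cells (mostly LYZ), 47.2 to 106 for stroma, 2.70 to 7.35 for endothelium and 78.8 to 353 for lung and gut. No 2 libraries of the same group were copies of each other (chi-square per gene at least 1.79). Floors for genes with 0 counts were set at 3 counts per library (0.131 CPM in vehicle, 0.12 CPM at the low dose of Aucklandiae Radix), and these floors cover counting error only.

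Comparisons, lists, the panel, the rule for naming genes and the alternatives were fixed before the data were examined, except the alternatives given below as chosen after seeing the data. Genes were tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test, after TMM scaling and the filterByExpr filter with a minimum count of 10. The fit had 57 libraries in 22 groups, 35 residual degrees of freedom and 16982 genes, and a common dispersion of 0.00216, a coefficient of variation of 4.7%. Okbyeongpung-san, with 1 library per dose, was not in the fit. Contrasts were each dose against vehicle, high against low dose, and 2 pairs of extracts of the same set at 500 ug/mL. The Benjamini-Hochberg adjusted p was called under 0.05 per contrast. For 8 panel genes the difference in dose response between extracts of a set was tested, adjusted over 16 tests. Log2 CPM used a prior count of 2.

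Gene lists were tested with camera (limma 3.58.1, correlation 0.01), adjusted over 147 tests per contrast. The 24 lists were targets of AHR, of PXR and CAR, of NRF2, of p53 and of ATF4 (integrated stress response), the ER unfolded protein response, heat shock, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation with PPARA targets, mitosis, DNA replication, hypoxia, secreted hepatocyte proteins, acute phase with NF-kB targets, gluconeogenesis with FOXO targets, bile acid handling, metallothioneins (with the zinc exporter SLC30A1), immediate early genes, mitochondrially encoded genes, and markers of blood, stromal, endothelial, and lung and gut cells. Of these, 21 had at least 5 tested genes. For Okbyeongpung-san, list medians were placed among 10000 random lists matched in 20 bins of expression. Decoctions and herbs were compared by Pearson correlation across genes, with an exact permutation of herb names.

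Named genes were, for each tested extract, the 5 highest and 5 lowest log2 fold changes against vehicle among genes called in the same direction against vehicle and against the low dose, with at least 5 CPM in the higher group and a gene symbol. Added to these were the panel CYP1A1, CYP3A4, HMOX1, TRIB3, HMGCS1, CDKN1A, MKI67 and ALB, and up to 3 members of each called list with the largest changes. Some genes that met this rule are not reported here. For Okbyeongpung-san the rule was a log2 difference of at least 1 from both vehicle and low dose with at least 5 CPM.

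Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter at a mean of 1 CPM, a fit of only the 2 groups, the replicate number as a block, and each library left out in turn. When this left an arm with 1 library, that library was assumed to vary like the other groups. Lists were also tested with an estimated correlation, with fry and for high against low dose. Correlations were also taken against vehicle, with Spearman, for genes of at least 10 CPM and for genes called in any extract. For Okbyeongpung-san RLE and a prior count of 5 were tried. Alternatives chosen after seeing the data were a pooled low-dose reference (the mean of the 7 low-dose groups in place of vehicle), leaving out mitochondrially encoded genes, removing each library's trend over GC content and transcript length, and leaving out each library for the differences in dose response between 2 extracts.

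The steps were tested on simulated data with the depth and spread of the real libraries (16539 genes). For Menthae Herba at 500 ug/mL against vehicle, 63.9% of genes changed by 0.5 and 82.5% of genes changed by 1 on the log2 scale were called, with 3 unchanged genes called. For Polygalae Radix at 250 ug/mL (2 libraries) these were 64.6%, 82.3% and 8.

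For lists in the same simulation, the limma camera p-value was 9.39e-38 for a list changed by 0.5 and 0.374 for an unchanged list. Across only the 109 genes given a change and with a mean of at least 10 CPM, the correlation was 0.991 for shared and -0.0814 for unshared changes. The correlation over all genes, as used for decoctions and herbs, was not simulated. List percentiles were 100 for a changed and 81 for an unchanged list. A GC trend put into vehicle alone made edgeR call 4660 unchanged genes for Saengmaek-san at 500 ug/mL, and 0 after its removal.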

Results

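RNA sequencing measured gene expression in HepG2, an established human hepatocellular carcinoma cell line, after 24 h with extracts of 4 herbs or 4 herbal decoctions. The herbs were Polygalae Radix, Aucklandiae Radix, Menthae Herba and Saposhnikoviae Radix, and the decoctions, which each combine several herbs, were Saengmaek-san, Guibi-tang, Soyo-san and Okbyeongpung-san. Each extract was given at 3 doses in steps of 5. The doses were 250, 50 and 10 ug/mL for Polygalae Radix, 280, 56 and 11.2 ug/mL for Aucklandiae Radix, and 500, 100 and 20 ug/mL for the others. High doses were the concentration giving 20% inhibition, or 500 ug/mL, so those of Polygalae Radix and Aucklandiae Radix were set by inhibition. Vehicle (DMSO) had 3 libraries. Menthae Herba, Saposhnikoviae Radix, Saengmaek-san and Guibi-tang had 3 libraries per dose, Polygalae Radix, Aucklandiae Radix and Soyo-san had 2, and Okbyeongpung-san had 1. The 60 libraries held a median of 23.7 M counts. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The study asks which genes each extract changes in these cells and how the decoctions relate to their herbs.

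Every tested extract differed from vehicle in at least 6592 genes at its high dose, but the difference between the high and the low dose of the same extract varied widely. The 2 extracts with the most genes, Aucklandiae Radix and Polygalae Radix, were those whose high dose was set by inhibition. Their counts therefore cannot separate the extract from inhibition of the cells. Polygalae Radix at 250 ug/mL had 11357 of 16982 tested genes past an edgeR Benjamini-Hochberg adjusted p of 0.05 against vehicle, and 10887 against its own low dose. Aucklandiae Radix at 280 ug/mL had 12447 and 11787, Guibi-tang at 500 ug/mL 8656 and 5821, and Menthae Herba 8185 and 3954. Soyo-san had 6592 against vehicle and 671 against its low dose. Saposhnikoviae Radix had 6811 and 141, and Saengmaek-san 6872 and 74. The counts of 671, 141 and 74 depended on single libraries and on settings, at 326 without Soyo-san high-dose replicate 2, 55 without Saposhnikoviae Radix low-dose replicate 3 and 47 without Saengmaek-san high-dose replicate 2, and they were 1100, 409 and 186 with the GC and length trend removed. Without a low-count filter they were 754, 250 and 253, and with only the 2 groups in the fit 801, 330 and 86. With the pooled low doses in place of vehicle, the high doses of these 3 extracts had 1521, 503 and 165 genes. Changes of at least 2-fold against vehicle were 2636 higher and 2559 lower in Aucklandiae Radix, 1202 and 2153 in Polygalae Radix, 295 and 523 in Guibi-tang, 172 and 390 in Menthae Herba, 116 and 253 in Soyo-san, 75 and 174 in Saengmaek-san and 62 and 173 in Saposhnikoviae Radix. Medium doses had 4404 to 7348 genes against vehicle and low doses 5656 to 6807, the lowest count being that of Polygalae Radix at 50 ug/mL, which was 2297 without its replicate 3 and 1272 with only the 2 groups in the fit. Soyo-san at 20 ug/mL had 5805, or 3667 without its replicate 2.

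**Figure D1:**
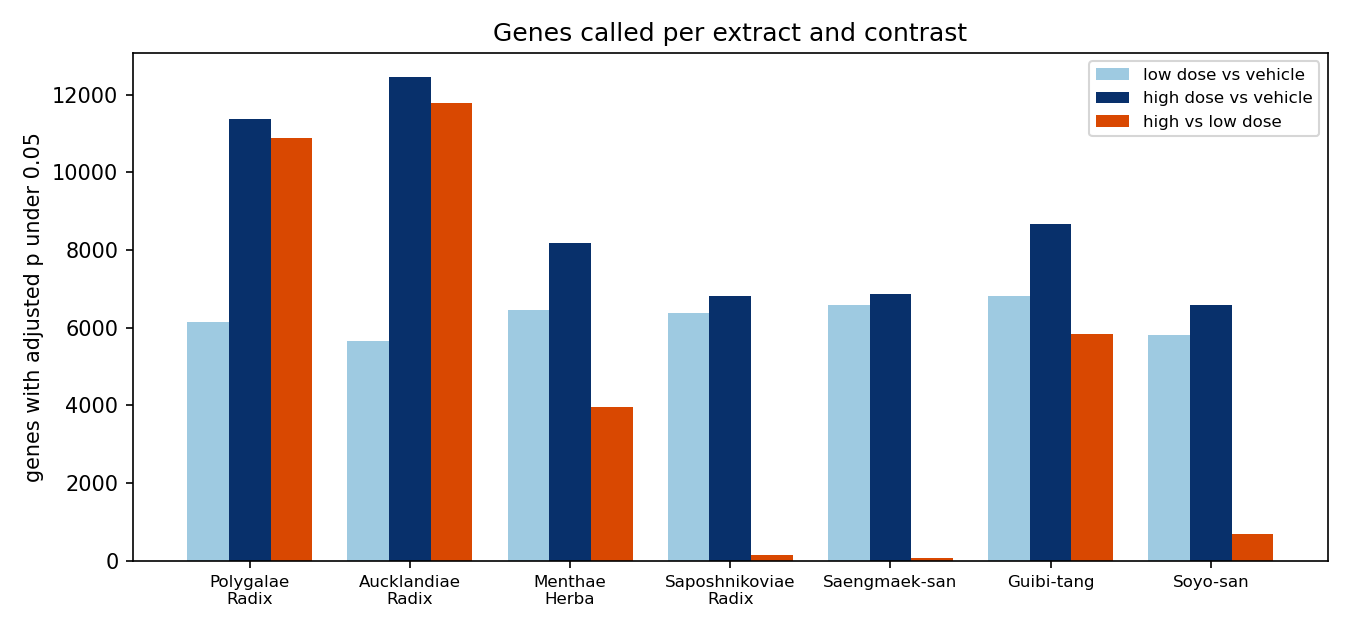
Number of genes past the threshold (y axis) for each tested extract (x axis), with bars for low dose against vehicle, high dose against vehicle and high against low dose. The bar for high against low dose is nearly as tall as that for high dose against vehicle in Polygalae Radix and Aucklandiae Radix, and short in Saposhnikoviae Radix (141 genes) and Saengmaek-san (74 genes).

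A large part of the counts against vehicle was common to all extracts at their lowest doses. At the low dose, 1811 genes were higher and 1799 lower than vehicle in all 7 tested extracts. Simulated unchanged groups set against a shared simulated vehicle gave 0, but no simulated library had a GC trend. If the calls of the extracts were independent, 0.144 and 0.101 genes would be shared, although the real calls share the same vehicle. Neither figure allows for a technical difference common to the vehicle libraries. The covariance of low-dose log2 fold changes between extracts, a median over 21 pairs, was 0.118 against 0.0281 in the simulation, and the correlation 0.77 against 0.47. These shared differences were small, with a median absolute log2 fold change of 0.33 and 1.3% of the genes past 2-fold. The 13 mitochondrially encoded genes of the respiratory chain took part, with 11 of them lower at the low dose of all 7 extracts. Mitochondrial genes held 16.9% ± 1.9 of counts in vehicle (SD, n = 3), 11.6% to 13.2% in the low-dose groups, 17.6% ± 0.16 in Polygalae Radix at 250 ug/mL (n = 2) and 8.1% ± 0.11 in Aucklandiae Radix at 280 ug/mL (n = 2). Abundance also leaned on transcript GC content in the vehicle libraries, by 0.102 to 0.225 on the log2 scale per 10 percentage points of GC, relative to the mean of all libraries, against a median of -0.011 in the other 57 libraries. Those 57 ran from -0.15 to 0.181, so slopes of this size were not confined to vehicle. The high-dose libraries of Aucklandiae Radix stood at -0.15 and -0.125, and those of Polygalae Radix at 0.099 and -0.111. Vehicle carries its own set label, so set and treatment cannot be told apart against vehicle. Genes named below for the highest or lowest changes had to be called in the same direction against vehicle and against the low dose, while list members were chosen on their change against vehicle.

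**Figure D2:**
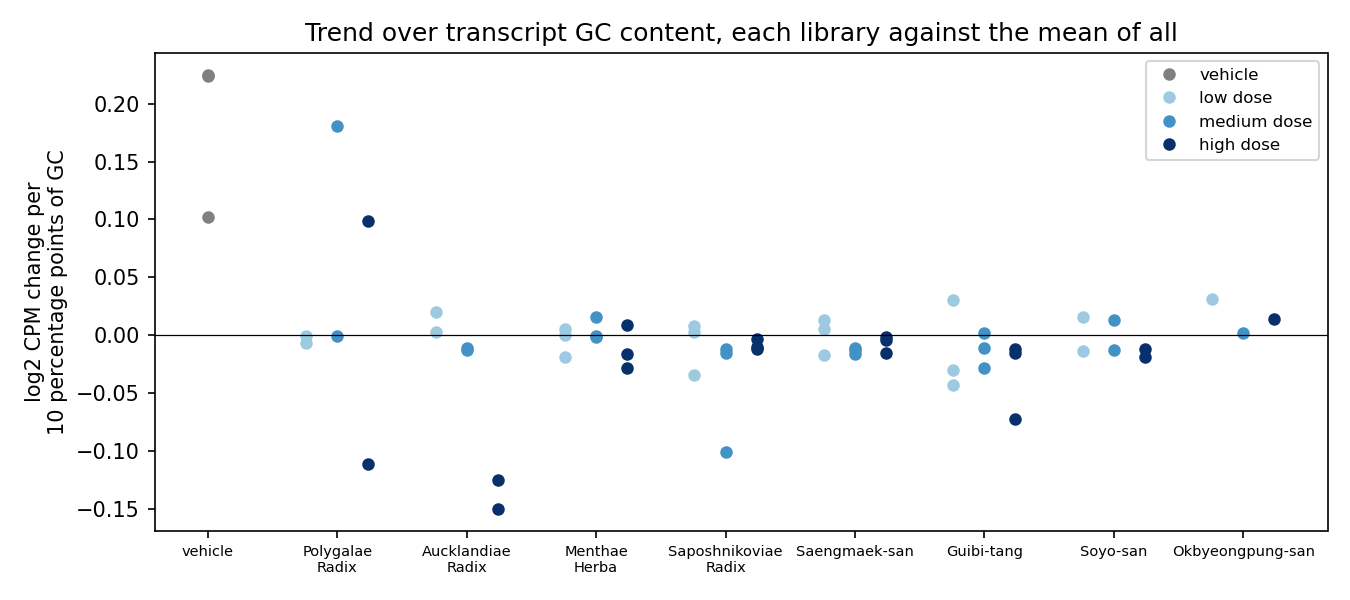
Slope of log2 CPM, relative to the mean of all libraries, over transcript GC content (y axis, log2 change per 10 percentage points of GC) for each library as a point, by extract and dose (x axis). The 3 vehicle points lie at 0.102 to 0.225, and 1 of the other 57 libraries lies above the lowest of them.

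CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (AHR), rose at the high dose of all 7 tested extracts against vehicle and against the low dose. The gene (ENSG00000140465) lies on the minus strand of chromosome 15 at 74719542 to 74725610 (GRCh38). Vehicle held 8.28 CPM. The level reached 223 ± 18.2 CPM with Soyo-san (SD, n = 2), 196 ± 5.79 with Guibi-tang (n = 3), 102 ± 5.63 with Polygalae Radix (n = 2), 86.6 ± 2.17 with Saposhnikoviae Radix (n = 3), 63 ± 3.75 with Menthae Herba (n = 3), 29.4 ± 0.661 with Saengmaek-san (n = 3) and 13.5 ± 4.27 with Aucklandiae Radix (n = 2). Log2 fold changes against vehicle in that order were 4.75, 4.57, 3.62, 3.39, 2.92, 1.83 and 0.7, with standard errors of 0.09 to 0.13, and against the low dose 3.9, 4.12, 3.52, 2.4, 3.25, 2.09 and 0.69. CYP1A1 had the highest log2 fold change of all genes meeting the naming rule in Saposhnikoviae Radix, Saengmaek-san, Guibi-tang and Soyo-san. Its rise over the low dose with Aucklandiae Radix was not past the threshold without replicate 3 of that high dose (log2 fold change 0.33, edgeR adjusted p = 0.05). Of the 8 tested AHR targets, 5 rose and 2 fell with Saposhnikoviae Radix (median 0.35, camera adjusted p = 0.00898), 5 rose with Guibi-tang (median 0.37, camera adjusted p = 0.00081), and 5 rose and 3 fell with Soyo-san (median 0.47, camera adjusted p = 0.0283, but adjusted p = 0.0568 with an estimated correlation). Counts adjusted over the list alone were the same. ALDH3A1, an aldehyde dehydrogenase, rose by 1.55 ± 0.25 (SE) with Saposhnikoviae Radix and 1.58 ± 0.28 with Soyo-san on the log2 scale, and by 1.51 and 1.61 against the low dose, from 0.598 CPM in vehicle.

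**Figure D3:**
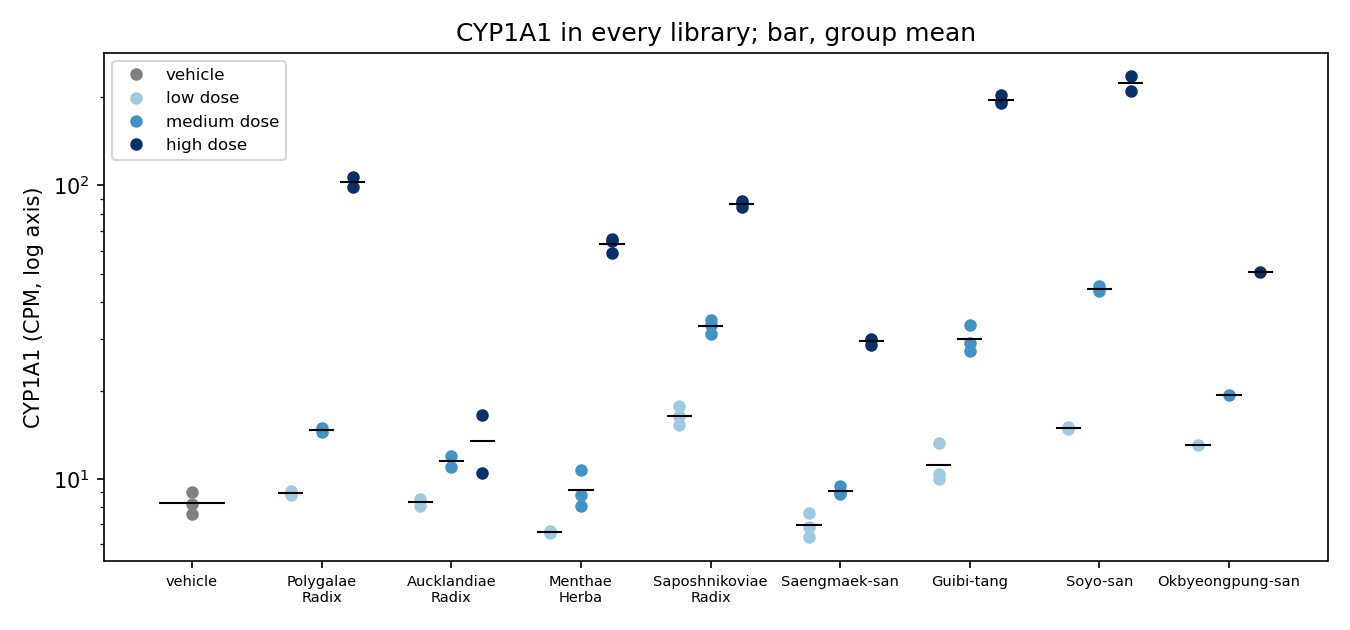
CYP1A1 level (y axis, CPM on a log axis) in each library as a point, by extract and dose (x axis), with a bar at each group mean. High-dose means run from 13.5 CPM in Aucklandiae Radix to 223 CPM in Soyo-san, above the vehicle mean of 8.28 CPM.

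The other genes fixed as a panel moved in different directions between extracts. HMOX1, heme oxygenase 1, went from 57.1 CPM in vehicle to 683 ± 31.1 with Aucklandiae Radix (SD, n = 2, log2 fold change 3.58) and 124 ± 3.31 with Guibi-tang (n = 3, 1.13), and it fell to 18.7 ± 2.06 with Polygalae Radix (n = 2, -1.61). Its values were -0.37 in Menthae Herba, 0.01 in Saposhnikoviae Radix, 0.05 in Saengmaek-san and -0.19 in Soyo-san, the last of which was -0.12 and no longer called without Soyo-san high-dose replicate 1. MKI67, a proliferation marker, fell against vehicle by 1.45, 1.67, 0.8 and 0.89 on the log2 scale with Polygalae Radix, Aucklandiae Radix, Menthae Herba and Guibi-tang, and by 1.04, 1.31, 0.45 and 0.53 against the low dose. In Saposhnikoviae Radix, Saengmaek-san and Soyo-san its changes from vehicle (-0.27, -0.38 and -0.39) had no counterpart against the low dose (0.06, 0.01 and -0.02). CDKN1A, the cell cycle inhibitor p21, rose with Aucklandiae Radix (1.91 against vehicle, 2.16 against low dose) and Guibi-tang (0.62 and 0.61). Against vehicle CDKN1A fell with Saposhnikoviae Radix (-0.41, but -0.15 and not called against the low dose) and rose with Soyo-san (0.31, but 0.19 and not called without high-dose replicate 1, and 0.24 and not called against the low dose). With Menthae Herba it rose against the low dose alone (0.3, but 0.24 and not called without high-dose replicate 1). In Polygalae Radix it was -0.11 and 0.12, neither called, yet -0.3 against vehicle without high-dose replicate 2 and 0.27 against the low dose without high-dose replicate 3 were called. Albumin (ALB) fell against the low dose by 1.33, 0.4, 0.45 and 0.59 with Polygalae Radix, Aucklandiae Radix, Menthae Herba and Guibi-tang. Against vehicle these changes of ALB were -1.06, -0.19, -0.04 (not called) and -0.24, that of Aucklandiae Radix was -0.15 and not called without high-dose replicate 3, and ALB was higher in Saposhnikoviae Radix (0.37), Saengmaek-san (0.47) and Soyo-san (0.22). These 3 differences were already there at the low dose (0.45, 0.44 and 0.39), and between the doses ALB had values of -0.08, 0.03 and -0.17, none past the threshold. In Soyo-san the value against vehicle was -0.03 with the GC trend removed. TRIB3, a target of the integrated stress response, rose with Aucklandiae Radix (0.77 and 0.94). Its values of -0.4, -0.33, -0.37 and -0.28 against vehicle in Polygalae Radix, Saposhnikoviae Radix, Guibi-tang and Soyo-san became -0.04, -0.13, -0.13 and -0.07, none past the threshold, once the GC trend was removed. Against the low dose TRIB3 was also called lower with Polygalae Radix (-0.35, but -0.25 and not called without high-dose replicate 3) and Guibi-tang (-0.22). The call in Guibi-tang was lost without high-dose replicate 1 (-0.22) or 2 (-0.16) or low-dose replicate 1 (-0.21) or 3 (-0.17). With the GC trend removed both were -0.19 and called. CYP3A4, a drug-metabolising enzyme, had a mean of 0.183 CPM in vehicle and 0.0967 to 0.5 CPM at the high doses. The log2 fold change of CYP3A4 was 1.39 with Aucklandiae Radix (edgeR adjusted p = 0.038), but 0.93 and not called against the low dose. Against vehicle it was not called with DESeq2 (1.46) or with the GC trend removed (1.21), and its call was lost without vehicle replicate 2 (1.37), vehicle replicate 3 (1.1) or high-dose replicate 2 (1.12).

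**Figure D4:**
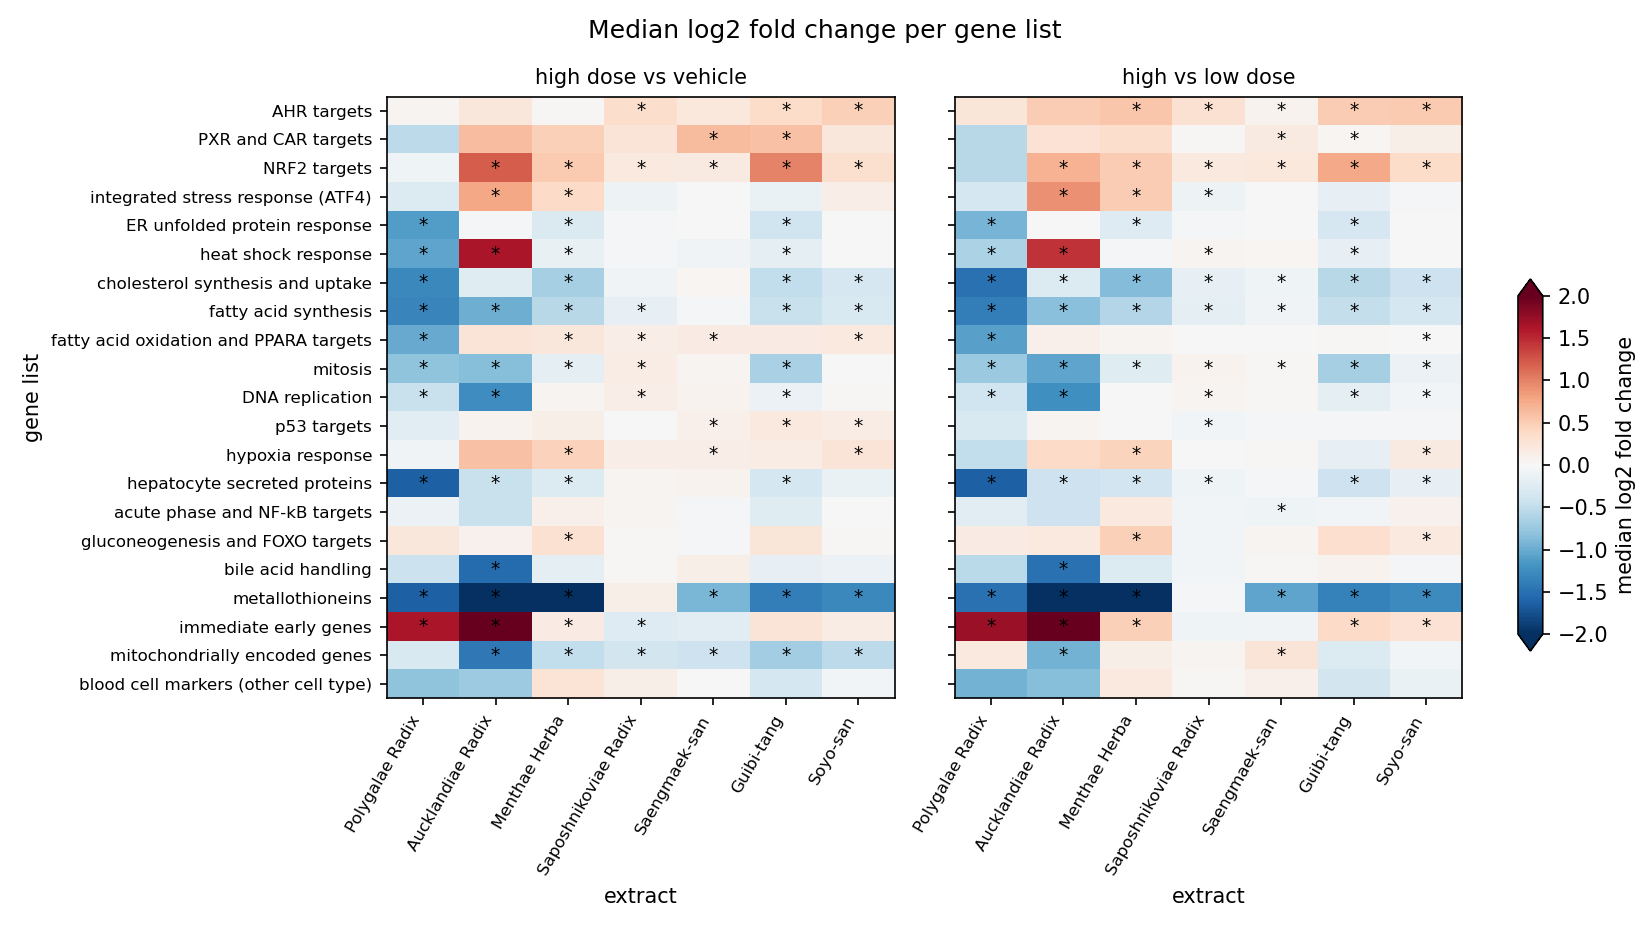
Median log2 fold change (colour) of each gene list (rows) in each tested extract (columns), for the high dose against vehicle (left) and against the low dose (right). An asterisk marks a camera adjusted p under 0.05, and the list of cholesterol genes carries one in all 7 columns on the right.

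Polygalae Radix at 250 ug/mL (n = 2) raised immediate early genes and lowered genes of secreted proteins, lipid metabolism and the unfolded protein response. EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 138465490 to 138469315), rose from 7.86 to 133 ± 30.5 CPM, 16.9-fold against vehicle (log2 fold change 4.08, SE 0.11, edgeR adjusted p = 2.3e-32) and 3.51 against the low dose. METRNL, which encodes a secreted protein, RASD1, a small GTPase, and EREG, a ligand of the epidermal growth factor family, rose 15.1-fold, 14.2-fold and 12.8-fold. MAGED1 (ENSG00000179222, chromosome X, 51803007 to 51902357) went from 487 to 25.7 ± 1.7 CPM, 18.9-fold lower than vehicle (-4.24, SE 0.06, edgeR adjusted p = 1.5e-42), and its relative MAGED2 was 11.8-fold lower. ZACN stood at 17.2 ± 2.41 CPM against 0.134 in vehicle. Its rise over the low dose (3.04) was lost with DESeq2 (2.76) and without low-dose replicate 3 (1.8) or high-dose replicate 2 (2.86). The read-through gene ATP6V1G2-DDX39B and SLX1B, which has a near-identical copy, had log2 fold changes of -3.45 and -3.32 with an SD above the mean at the high dose (7.96 and 6.98 CPM), so reads may be divided between gene copies differently in the 2 libraries.

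Of 14 immediate early genes 13 rose with Polygalae Radix (median log2 fold change 1.63, camera adjusted p = 1.47e-07), among them FOS (3.4) and JUN (2.39). All 21 secreted hepatocyte proteins fell (median -1.63, camera adjusted p = 5.25e-14). They included vitronectin (VTN, -3.31), antithrombin (SERPINC1, -2.55) and alpha-1 antitrypsin (SERPINA1, -2.45). All 15 fatty acid synthesis genes fell (median -1.32, camera adjusted p = 3.13e-10), with FADS2 at -2.63, the citrate-cleaving enzyme ACLY at -2.56 and ACSS2 at -2.47. Of 24 cholesterol genes 22 fell and 1 rose (median -1.29, camera adjusted p = 2.07e-11), with DHCR7 at -1.91, LSS at -1.9 and HMGCS1 at -1.76. Fatty acid oxidation fell in 14 of 18 members and rose in 1 (median -1.01, camera adjusted p = 9.15e-06), with HADHA at -2.49 and EHHADH at -2.03. Of 18 genes of the endoplasmic reticulum (ER) unfolded protein response 16 fell and 2 rose (median -1.11, camera adjusted p = 3.19e-07), including the chaperones PDIA4 (-2.71), CALR (-2.64) and HSPA5 (-2.57). These 6 calls held with an estimated correlation. Heat shock genes fell in 16 of 18 members (median -1.06, camera adjusted p = 1.1e-05, adjusted p = 0.0568 with an estimated correlation), with HSP90AA1 at -2.44. Mitosis genes fell in 21 of 24 members and rose in 2 (median -0.8, camera adjusted p = 2.57e-07, adjusted p = 0.0645 with an estimated correlation), with TOP2A at -1.97. DNA replication genes fell in 15 of 24 and rose in 6 (median -0.44, camera adjusted p = 0.00195, adjusted p = 0.138 with an estimated correlation), with MCM2 at -1.87 and the cyclin CCNE2 at 1.81. All 7 metallothioneins, small metal-binding proteins, fell, and the zinc exporter SLC30A1 on the same list did not (median -1.63, camera adjusted p = 0.00766, adjusted p = 0.237 with an estimated correlation). All 10 lists were also called in the same direction against the low dose, and counts adjusted over the list alone were the same.

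Aucklandiae Radix at 280 ug/mL (n = 2) raised heat shock, immediate early and oxidative stress genes and lowered genes of DNA replication and fatty acid synthesis. HSPA6, an inducible heat shock protein (ENSG00000173110, chromosome 1, 161524540 to 161526910), reached 209 ± 44.2 CPM from 0 counts in vehicle, at least 1590-fold higher at a floor of 3 counts per library. It has a close copy in the genome, so its reads may be shared. CCL26, a chemokine, reached 6.52 ± 0.66 CPM from 0 counts in both references, at least 49.6-fold above vehicle and 54.4-fold above the low dose. ARC, an activity-regulated gene, KPNA7, an importin, and the carbonic anhydrase CA2 reached 17.7, 10.2 and 7.62 CPM from under 0.08 CPM in vehicle. SPTLC3, a subunit of serine palmitoyltransferase (ENSG00000172296, chromosome 20, 13008979 to 13169103), went from 60.8 to 1.66 ± 0.284 CPM, 36.4-fold lower (-5.19, SE 0.09, edgeR adjusted p = 1.4e-39). TRIM50 was 37-fold lower. CDRT4, which overlaps a read-through gene, and the antisense gene TUBA1B-AS1 had log2 fold changes of -6.78 and -8.72. TUBA1B-AS1 was at 116 CPM in vehicle but 6.57 in the low dose, and its difference from the pooled low doses was -1.7 and not past the threshold.

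All 18 heat shock genes rose with Aucklandiae Radix (median 1.63, camera adjusted p = 1.98e-10), with HSPA1A at 3942 ± 793 CPM (4.81), its near-identical copy HSPA1B at 4.3 and HSPH1 at 3.6. Of 14 immediate early genes 13 rose and 1 fell (median 2.84, camera adjusted p = 4.02e-07), with FOS at 6.33, FOSB at 5.76 and the phosphatase DUSP1 at 3.92. Targets of the oxidative stress factor NRF2 rose in 16 of 21 members and fell in 2 (17 and 2 adjusted over the list alone, median 1.21, camera adjusted p = 6.57e-06). HMOX1 (3.58), the glutathione synthesis gene GCLM (3.24) and SRXN1 (2.94) led this list. DNA replication genes fell in 21 of 24 and rose in 2 (median -1.25, camera adjusted p = 5.34e-09), with UHRF1 at -2.84, and fatty acid synthesis genes fell in 13 of 15 and rose in 2 (median -0.97, camera adjusted p = 1.34e-05), with GPAM at -2.87 and SREBF1 at -1.61. These 5 lists held with an estimated correlation. Integrated stress response genes rose in 18 of 23 and fell in 4 (median 0.77, camera adjusted p = 0.00608, adjusted p = 0.473 with an estimated correlation), among them ATF3 (3.81), GDF15 (3.03) and ASNS (2.71). Mitosis genes fell in 22 of 24 and rose in 2 (median -0.85, camera adjusted p = 7.74e-08, adjusted p = 0.0568 with an estimated correlation), with KIF20A at -1.75 and PLK1 at -1.72. Secreted hepatocyte proteins fell in 19 of 21 (median -0.45, camera adjusted p = 0.000415, adjusted p = 0.288 with an estimated correlation), with apolipoprotein B (APOB) from 29100 to 6526 ± 672 CPM. Bile acid genes fell in 6 of 9 and rose in 2 (median -1.54, camera adjusted p = 0.0281, adjusted p = 0.15 with an estimated correlation), including CYP8B1 (-3.41) and the bile acid receptor NR1H4 (-2.75). All 7 metallothioneins fell and SLC30A1 rose (median -2.1, camera adjusted p = 0.0114, adjusted p = 0.27 with an estimated correlation), but SLC30A1 was at 0.13 and not called against the low dose. All 13 mitochondrially encoded genes fell (median -1.43, camera adjusted p = 0.000101, adjusted p = 0.353 with an estimated correlation), with MT-CO1 at -2.06 against vehicle and -1.69 against the low dose. Counts for the other lists adjusted over the list alone were the same, and all 11 lists were called in the same direction against the low dose.

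Menthae Herba at 500 ug/mL (n = 3) raised CYP1A1 and NRF2 targets, and lowered metallothioneins, cholesterol and fatty acid synthesis genes. IGFBP1, a secreted insulin-like growth factor binding protein (ENSG00000146678, chromosome 7, 45888357 to 45893668), rose from 24.8 to 195 ± 10.5 CPM, 7.9-fold against vehicle (2.98, SE 0.22, edgeR adjusted p = 2.6e-15) and by 2.27 against the low dose. The glucose-6-phosphatase gene G6PC1 rose 5.79-fold, the stress-induced DDIT4 4.98-fold and the aldo-keto reductase AKR1B10 3.37-fold. MT1G, a metallothionein (ENSG00000125144, chromosome 16, 56666731 to 56668065), went from 63.1 to 6.26 ± 0.117 CPM, 10.1-fold lower (-3.33, SE 0.12, edgeR adjusted p = 2.8e-26), and MT1F, MT1X and MT1E were 6.78-fold, 5.53-fold and 5.21-fold lower. APOB went from 29100 to 7483 ± 1387 CPM (-1.96 against vehicle, -1.86 against the low dose).

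All 8 genes of the metallothionein list fell with Menthae Herba, SLC30A1 included (median -2.42, camera adjusted p = 1.98e-10). Cholesterol genes fell in 23 of 24 (median -0.66, camera adjusted p = 1.92e-21), with MVD at -1.31, LSS at -1.17 and HMGCS1 at -1.07. Fatty acid synthesis genes fell in 14 of 15 and rose in 1 (median -0.56, camera adjusted p = 3.13e-13), with FADS2 at -1.56 and ACSS2 at -1.28. NRF2 targets rose in 15 of 21 and fell in 2 (16 and 3 adjusted over the list alone, median 0.53, camera adjusted p = 9.48e-09), led by AKR1B10 (1.75) and AKR1C1 (1.32), which shares sequence with AKR1C2. Genes of fatty acid oxidation rose in 10 of 18 and fell in 1 (median 0.23, camera adjusted p = 0.00139), with PLIN2 at 0.88 and CPT1A at 0.71. These 5 lists held with an estimated correlation. Integrated stress response genes rose in 19 of 23 and fell in 1 (20 and 1 adjusted over the list alone, median 0.39, camera adjusted p = 1.17e-06, adjusted p = 0.174 with an estimated correlation), with GDF15 at 1.54. Hypoxia genes rose in 16 of 20 (median 0.46, camera adjusted p = 5.71e-07, adjusted p = 0.0828 with an estimated correlation), with PDK1 at 1.21 and BNIP3 at 1.08, and 0.69 and 0.55 against the low dose. Gluconeogenesis genes rose in 7 of 11 (7 rose and 1 fell adjusted over the list alone, median 0.31, camera adjusted p = 0.0213, adjusted p = 0.0691 with an estimated correlation). Immediate early genes rose in 6 of 14 and fell in 1 (median 0.17, camera adjusted p = 0.0226, adjusted p = 0.36 with an estimated correlation), with IER3 at 1.04. ER unfolded protein response genes fell in 12 of 18 and rose in 3 (13 and 3 adjusted over the list alone, median -0.29, camera adjusted p = 1.22e-05, adjusted p = 0.0588 with an estimated correlation), with HYOU1 at -0.85. Secreted hepatocyte proteins fell in 14 of 21 and rose in 1 (median -0.27, camera adjusted p = 3.46e-05, adjusted p = 0.21 with an estimated correlation), and mitosis genes fell in 15 of 24 and rose in 1 (median -0.19, camera adjusted p = 9.57e-05, adjusted p = 0.174 with an estimated correlation). Heat shock genes fell in 9 of 18 and rose in 3 (median -0.15, camera adjusted p = 0.0485, adjusted p = 0.4 with an estimated correlation), but HSPA1A at -1.0 was -0.22 and not called against the low dose. Of 13 mitochondrially encoded genes 12 fell (13 adjusted over the list alone, median -0.49, camera adjusted p = 0.000186, adjusted p = 0.36 with an estimated correlation), while against the low dose their mean was 0.09. The remaining counts were the same adjusted over the list alone, and heat shock, fatty acid oxidation and mitochondrially encoded genes were the 3 lists not called in that direction against the low dose.

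Saposhnikoviae Radix at 500 ug/mL (n = 3) raised CYP1A1 and aldo-keto reductases, and few other genes differed from its low dose. AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408) rose from 40.2 to 75.9 ± 1.33 CPM (0.93 against vehicle, SE 0.06, 0.57 against the low dose). AKR1C2 and AKR1C1, near-identical relatives, rose by 0.92 and 0.88, and the lectin MBL2 was higher by 0.81. NGFR, the p75 neurotrophin receptor, was lower (log2 fold change -1.15, SE 0.12), as were WNK4 (-0.8), SV2A (-0.8), PDGFRB (-0.78) and HID1 (-0.77). Against the low dose, the calls of MBL2 (0.35), NGFR (-0.54), WNK4 (-0.43), SV2A (-0.41), PDGFRB (-0.49) and HID1 (-0.52) were each lost when 1 library was left out, and any of several libraries did so for all but WNK4. Without low-dose replicate 3 they were -0.42 for NGFR, -0.43 for PDGFRB and -0.44 for HID1, without low-dose replicate 1 -0.31 for SV2A, without high-dose replicate 1 -0.41 for WNK4, and without high-dose replicate 2 0.31 for MBL2. NRF2 targets rose in 11 of 21 and fell in 2 (median 0.19, camera adjusted p = 1.34e-05). Fatty acid synthesis genes fell in 9 of 15 and rose in 1 (10 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.000135), with FADS2 at -0.56 and -0.37 against the low dose. Both held with an estimated correlation, as did the AHR list. Fatty acid oxidation genes rose in 7 of 18 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.07 with an estimated correlation). Mitosis genes rose in 12 of 24 and fell in 2 (13 and 3 adjusted over the list alone, camera adjusted p = 0.00428, adjusted p = 0.341 with an estimated correlation), and DNA replication genes rose in 14 of 24 and fell in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.281 with an estimated correlation). Immediate early genes fell in 6 of 14 (camera adjusted p = 0.0313, adjusted p = 0.376 with an estimated correlation) and mitochondrially encoded genes in 11 of 13 (camera adjusted p = 0.00087, adjusted p = 0.408 with an estimated correlation). With the GC trend removed the mitosis list (mean 0.01, median 0.03, camera adjusted p = 0.506) and the immediate early genes (camera adjusted p = 0.217) were not called. Against the low dose the AHR, NRF2, fatty acid synthesis, mitosis and DNA replication lists were called in the same direction, but CDK1 (0.51) and TYMS (0.25) were at -0.01 and 0.02. Other counts were the same adjusted over the list alone.

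Saengmaek-san at 500 ug/mL (n = 3) raised CYP1A1, AKR1B10 and genes of drug metabolism and lowered metallothioneins. AKR1B10 rose to 79.3 ± 1.14 CPM (0.99 against vehicle, 0.72 against the low dose), AKR1C2 by 0.74 and the zinc importer SLC39A10 by 0.78 (0.51 against the low dose). TNS4, an adhesion protein (ENSG00000131746, chromosome 17, 40475828 to 40501597), went from 46.6 in vehicle to 23.2 CPM at the low dose and 16.3 ± 0.454 at the high dose (-1.51, SE 0.09, -0.51 against the low dose). All 3 metallothioneins with the largest changes that met the naming rule fell, MT1G by 1.33, MT2A by 1.22 and MT1X by 0.92. The metallothionein list fell in 6 of 8 members (median -0.91, camera adjusted p = 9.15e-06), NRF2 targets rose in 11 of 21 and fell in 2 (median 0.18, camera adjusted p = 1.9e-05), and targets of the drug receptors PXR and CAR rose in 4 of 9 and fell in 1 (median 0.64, camera adjusted p = 0.00785). These 3 lists held with an estimated correlation. In the PXR and CAR list the transporter ABCC2 rose by 0.64 (0.36 against the low dose), and CYP3A5 by 0.74, while its call against the low dose (0.55) was lost without low-dose replicate 3 (0.48), low-dose replicate 2 or high-dose replicates 1 or 2. Fatty acid oxidation genes rose in 10 of 18 and fell in 2 (camera adjusted p = 0.0252, adjusted p = 0.0828 with an estimated correlation), and p53 targets rose in 9 of 22 and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0474, adjusted p = 0.0693 with an estimated correlation). Hypoxia genes rose in 8 of 20 and fell in 1 (camera adjusted p = 0.0313, adjusted p = 0.493 with an estimated correlation), and mitochondrially encoded genes fell in 11 of 13 (camera adjusted p = 0.000336, adjusted p = 0.376 with an estimated correlation). None of these 4 lists was called in that direction against the low dose. The p53 targets BTG2 (0.49) and CCNG1 (0.45) were at 0.08 and 0.05 against the low dose. Other counts were the same adjusted over the list alone.

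Guibi-tang at 500 ug/mL (n = 3) raised AHR, NRF2, PXR and CAR targets, and lowered genes of mitosis and of cholesterol and fatty acid synthesis. GSTA2, a glutathione transferase with close relatives (ENSG00000244067, chromosome 6, 52750089 to 52763569), rose from 5.47 to 56.8 ± 5.88 CPM, 10.4-fold (3.38, SE 0.1, edgeR adjusted p = 2.5e-29) and by 2.52 against the low dose. PTGR1, prostaglandin reductase 1, rose 7.79-fold, FXYD1 6.35-fold and AKR1C2 6.17-fold. NGFR was 5.51-fold lower, the sulfatase gene ARSI 5.03-fold, PRR36 4.98-fold, TXNIP 4.07-fold and the sodium channel gene SCN1A 3.89-fold, each also lower than at the low dose. PRR36 had 8.04 CPM in vehicle and 3.37 at the low dose. NRF2 targets rose in 17 of 21 and fell in 1 (median 0.99, camera adjusted p = 1.28e-15), with AKR1C1 at 2.41 and AKR1B10 at 2.31. PXR and CAR targets rose in 5 of 9 and fell in 1 (median 0.58, camera adjusted p = 0.00139), with ABCC2 at 1.25 and SULT2A1 at 1.22. Mitosis genes fell in 23 of 24 (median -0.65, camera adjusted p = 1.28e-15), with PLK1 at -1.19 and UBE2C at -1.06. Cholesterol genes fell in 18 of 24 and rose in 1 (19 and 2 adjusted over the list alone, median -0.49, camera adjusted p = 4.56e-10), with MVD at -0.88 and FDFT1 at -0.84, and fatty acid synthesis genes fell in 12 of 15 (13 adjusted over the list alone, median -0.45, camera adjusted p = 4.66e-10), with FADS2 at -1.44. These and the AHR list held with an estimated correlation. Secreted hepatocyte proteins fell in 17 of 21 (18 adjusted over the list alone, median -0.35, camera adjusted p = 1.97e-08, adjusted p = 0.07 with an estimated correlation), with VTN at -1.12 and the fibrinogen gene FGB at -0.87. All 7 metallothioneins fell and SLC30A1 rose (median -1.38, camera adjusted p = 4.85e-05, adjusted p = 0.0638 with an estimated correlation), but SLC30A1 was at -0.03 and not called against the low dose. ER unfolded protein response genes fell in 14 of 18 and rose in 3 (median -0.4, camera adjusted p = 1.64e-05, adjusted p = 0.0638 with an estimated correlation), with CALR at -0.82, and heat shock genes fell in 10 of 18 and rose in 4 (median -0.19, camera adjusted p = 0.0313, adjusted p = 0.368 with an estimated correlation), with HSPB1 at -1.37. DNA replication genes fell in 13 of 24 and rose in 3 (median -0.12, camera adjusted p = 0.00357, adjusted p = 0.16 with an estimated correlation), and p53 targets rose in 12 of 22 and fell in 3 (median 0.2, camera adjusted p = 0.0313, adjusted p = 0.0568 with an estimated correlation), with GDF15 at 1.11. All 13 mitochondrially encoded genes fell (median -0.7, camera adjusted p = 1.59e-05, adjusted p = 0.288 with an estimated correlation). Against the low dose that list and the p53 targets were not called, and the other counts were the same adjusted over the list alone.

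Soyo-san at 500 ug/mL (n = 2) raised CYP1A1, IGFBP1 and AKR1B10 and lowered metallothioneins. IGFBP1 rose to 94.6 ± 1.9 CPM (1.94, SE 0.25, 1.65 against the low dose), AKR1B10 3.21-fold, and MYOF, a membrane repair protein, 3.04-fold (ENSG00000138119, chromosome 10, 93306429 to 93482317). NQO1, a quinone reductase, rose from 371 to 785 ± 22.2 CPM (1.09, and 0.72 against the low dose). Among genes with a symbol, at least 5 CPM and calls below both vehicle and the low dose, the 5 largest falls were all metallothioneins. They were MT1G (-1.76), MT1F (-1.41), MT1X (-1.39), MT2A (-1.19) and MT1E (-1.16). The metallothionein list fell in 6 of 8 members (median -1.29, camera adjusted p = 4.02e-07). NRF2 targets rose in 14 of 21 and fell in 3 (median 0.32, camera adjusted p = 1.12e-07). Cholesterol genes fell in 15 of 24 and rose in 1 (median -0.33, camera adjusted p = 6.72e-07), with MVD at -0.72, and fatty acid synthesis genes fell in 13 of 15 and rose in 1 (median -0.3, camera adjusted p = 3.54e-08), with FADS2 at -0.85. Fatty acid oxidation and PPARA targets rose in 9 of 18 and fell in 2 (median 0.19, camera adjusted p = 0.00591), with the pantetheinase VNN1 at 1.58, and p53 targets rose in 11 of 22 and fell in 2 (median 0.15, camera adjusted p = 0.00805), with GDF15 at 1.04. These 6 lists held with an estimated correlation. Hypoxia genes rose in 13 of 20 (median 0.25, camera adjusted p = 0.000205, adjusted p = 0.225 with an estimated correlation), with PDK1 at 0.9, whose call against the low dose (0.48) was lost without low-dose replicate 1 (0.46) or high-dose replicate 2 (0.43). Of 13 mitochondrially encoded genes 12 fell (13 adjusted over the list alone, median -0.53, camera adjusted p = 1.72e-05, adjusted p = 0.288 with an estimated correlation), with MT-ND1 at -0.95 but -0.16 against the low dose. Other counts were the same adjusted over the list alone, and the p53 and mitochondrial lists were not called against the low dose.

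Across the 7 extracts 72 of 147 list tests were called against vehicle, 30 higher and 42 lower. Of these, 34 held with an estimated correlation, 58 were called in the same direction against the low dose, and 70 held with the GC trend removed, which also added 13 calls. Acute phase and NF-kB targets (12 tested genes, medians -0.45 to 0.1) and blood cell markers (6 tested genes, medians -0.81 to 0.27) were called in none. Stromal and endothelial markers had 4 tested genes each and the lung and gut markers 1 (VIL1), too few for a test. Stromal medians were -1.09 to -0.37, endothelial medians -1.3 to 0.06, and VIL1 was lowest in Polygalae Radix (-2.04) and Aucklandiae Radix (-2.12).

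Okbyeongpung-san had 1 library per dose, so its values have no replicate check and no test. At 500 ug/mL, 621 genes differed by at least 1 on the log2 scale from the vehicle mean (201 higher, 420 lower), 203 of them also from the low dose (54 higher, 149 lower), and 11 of these had at least 5 CPM. With a prior count of 5 the 621 and 203 became 317 and 77. CYP1A1 stood at 50.7 CPM against 13 at the low dose (differences of 2.61 from vehicle and 1.95 from the low dose), AKR1B10 at 115 CPM (1.52 and 1.14), and AKR1C2 at 558 CPM (1.4 and 1.14). MAGED4B, which has a near-identical copy, stood at 21.3 CPM (-1.14 and -1.54), but it varied widely between the vehicle libraries (53.8 ± 28.5 CPM, SD). Among 10000 random lists matched on expression, the median of the 21 NRF2 targets against the low dose (0.34) lay at percentile 100, that of the 8 AHR targets (0.19) at 99.8 and that of the PXR and CAR targets (0.17) at 99.9. Against vehicle with the GC trend removed the PXR and CAR targets lay at 87.2. Cholesterol genes (median -0.29, higher in 0 of 24) and fatty acid synthesis genes (-0.23, higher in 0 of 15) lay at percentile 0, as did secreted hepatocyte proteins (-0.06). Heat shock genes (0.09) lay at 99.5 and metallothioneins (-0.1) at 1.4. Against vehicle heat shock genes lay at 69.8, metallothioneins at 41.6, secreted hepatocyte proteins at 10, and cholesterol and fatty acid synthesis genes at 3.1 and 0.4. The mitochondrially encoded genes lay at percentile 100 against the low dose (0.13, higher in 13 of 13) and at percentile 0 against vehicle (-0.34).

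Extracts of the same sample set were compared at matched doses of 500 ug/mL. Saposhnikoviae Radix and Menthae Herba differed in 3600 genes, 2012 higher and 1588 lower in Saposhnikoviae Radix, and Guibi-tang and Saengmaek-san in 5744, 2865 higher and 2879 lower in Guibi-tang (edgeR, n = 3 each). The change from low to high dose differed in 1803 and 3320 genes. The rise of CYP1A1 from low to high dose was larger with Menthae Herba (3.25) than with Saposhnikoviae Radix (2.4), a difference of -0.85 ± 0.14 (SE, edgeR adjusted p = 3.4e-07 over 16 tests), and larger with Guibi-tang (4.12) than with Saengmaek-san (2.09), a difference of 2.03 ± 0.14 (edgeR adjusted p = 3.48e-17). In the first pair the low dose of Saposhnikoviae Radix already held 16.4 CPM of CYP1A1, 0.99 above vehicle on the log2 scale, against 6.6 CPM in that of Menthae Herba. At 500 ug/mL Saposhnikoviae Radix held more (86.6 against 63 CPM), so its smaller rise started from a higher level. The fall of HMGCS1, a cholesterol synthesis enzyme, was larger with Menthae Herba (-1.4 against -0.21) and with Guibi-tang (-0.92 against -0.18). HMOX1 rose more with Guibi-tang (1.38) than with Saengmaek-san (0.27), a difference of 1.12 ± 0.07 (edgeR adjusted p = 1.51e-18). The change of CYP3A4 was not shown to differ in either pair (edgeR differences of -0.31 ± 0.85 and -1.36 ± 0.8), nor was that of TRIB3 between Guibi-tang and Saengmaek-san (-0.21 ± 0.11, edgeR adjusted p = 0.0817). Each library was left out of these differences in turn, a check chosen after seeing the data. For Guibi-tang and Saengmaek-san, TRIB3 was then called without Guibi-tang low-dose replicate 2 (-0.26) or high-dose replicate 3 (-0.27), and CYP3A4 without that high-dose replicate 3 (-2.02).

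Decoctions were compared with their herbs through the correlation, across genes, of the change from low to high dose. Guibi-tang contains Polygalae Radix (r = 0.24) and Aucklandiae Radix (r = 0.37), Soyo-san contains Menthae Herba (r = 0.28) and Okbyeongpung-san contains Saposhnikoviae Radix (r = 0.09). Guibi-tang with Menthae Herba, a pair without that relation, reached r = 0.29, and the separate herbs Polygalae Radix and Aucklandiae Radix reached r = 0.35 with each other. The 4 constituent pairs had a mean r of 0.241 and the 12 other pairs 0.095. Of the 24 orders of the herb names 2 gave a difference this high, for a one-sided exact permutation p of 0.083, the smallest this design can give, so the threshold of 0.05 was out of reach. Genes are not independent replicates, and Okbyeongpung-san rests on 1 library per dose. Over genes with a mean of at least 10 CPM, r was 0.66 for Soyo-san and Menthae Herba, 0.58 for Okbyeongpung-san and Saposhnikoviae Radix, 0.46 for Guibi-tang and Aucklandiae Radix and 0.27 for Guibi-tang and Polygalae Radix. Of the other pairs, Saengmaek-san with Saposhnikoviae Radix (0.49) and Guibi-tang with Menthae Herba (0.42) were then highest. Called genes overlapped, with 1702 higher and 2136 lower against the low dose in both Guibi-tang and Aucklandiae Radix (970 and 1051 for independent lists) and 1013 in opposite directions. For Guibi-tang and Polygalae Radix 1314 were higher and 1799 lower in both (889 and 978 for independent lists) and 1450 opposite. For Soyo-san and Menthae Herba 277 were higher and 284 lower in both (39 and 39), and 15 opposite. Guibi-tang and Menthae Herba, without that relation, had 834 and 975 in both (309 and 370) and 479 opposite.

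**Figure D5:**
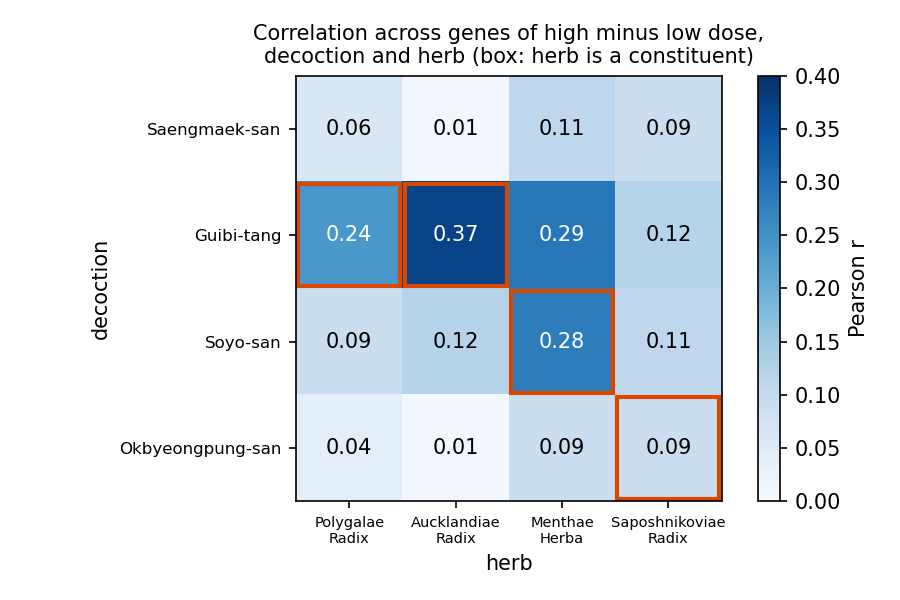
Pearson correlation across genes of the change from low to high dose between each decoction (y axis) and each herb (x axis), with the value in each cell and a box around pairs in which the herb is a constituent. Values run up to 0.37 for Guibi-tang and Aucklandiae Radix.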

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

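The results below were singled out because an edgeR test of the difference itself (16 tests, Benjamini-Hochberg) found that the change from 20 to 500 ug/mL differed between 2 extracts of the same sample set, with 3 libraries per dose. For Saposhnikoviae Radix minus Menthae Herba the differences on the log2 scale were -0.85 for CYP1A1 (adjusted p = 3.4e-07), 0.36 for HMOX1 (1.83e-05), -0.29 for TRIB3 (0.0159), 1.19 for HMGCS1 (3.48e-17), -0.45 for CDKN1A (5e-04), 0.51 for MKI67 (1.84e-08) and 0.37 for ALB (7.42e-06). The difference for TRIB3 was -0.11 and not called (edgeR adjusted p = 0.267) without Menthae Herba high-dose replicate 1, in a check chosen after seeing the data. CYP1A1 started from 16.4 CPM at the low dose of Saposhnikoviae Radix and from 6.6 CPM at that of Menthae Herba. HMGCS1, MKI67 and ALB fell with Menthae Herba (-1.4, -0.45 and -0.45), and in Saposhnikoviae Radix they were -0.21, 0.06 and -0.08.

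For Guibi-tang minus Saengmaek-san the differences were 2.03 for CYP1A1 (edgeR adjusted p = 3.48e-17), 1.12 for HMOX1 (1.51e-18), -0.73 for HMGCS1 (1.14e-10), 0.65 for CDKN1A (1.67e-06), -0.54 for MKI67 (6.21e-09) and -0.62 for ALB (1.14e-10). MKI67 and ALB fell with Guibi-tang (-0.53 and -0.59), and in Saengmaek-san they were 0.01 and 0.03.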

How the results depend on the processing

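With DESeq2, RLE, the filter at 1 CPM, or mitochondrially encoded genes left out, all 30 counts of called genes stayed within 1.5 times. Of 616 named results, called or not, 581 were the same with DESeq2, 6 weaker and 2 stronger, and 27 had no adjusted p. The replicate number as a block changed none of the 72 list calls and left 613 of 616 named results the same; no comparison behaved as paired (correlations -0.062 to 0.116), with MDM2 in Soyo-san (0.2) and MT-ND1 in Guibi-tang (-0.29) no longer called against the low dose. Leaving out 1 library left 3188 named results the same, with 100 weaker and 6 stronger. With an estimated correlation 34 of the 72 list calls held and 38 were lost; fry lost none and called 44 more. For the values below the cause was not tested.

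Without a filter, the counts for 500 against 20 ug/mL were 250 for Saposhnikoviae Radix and 253 for Saengmaek-san. With the GC and length trend removed they were 409, 186 and, for Soyo-san, 1100, and Saposhnikoviae Radix at 100 ug/mL against vehicle had 4587. Against the pooled low-dose reference the high dose had 503 genes in Saposhnikoviae Radix, 165 in Saengmaek-san and 1521 in Soyo-san. With only the 2 groups, Polygalae Radix at 50 ug/mL against vehicle had 1272 and Saposhnikoviae Radix at 500 against 20 ug/mL 330. Okbyeongpung-san had 77 genes with a prior count of 5. Leaving out 1 library gave 2297 to 4743 for Polygalae Radix at 50 ug/mL, 3667 to 6009 for Soyo-san at 20 ug/mL, and for high against low dose 55 to 102 in Saposhnikoviae Radix, 47 to 70 in Saengmaek-san and 326 to 414 in Soyo-san.

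Signs turned with the GC trend removed for CDKN1A in Polygalae Radix (0.28), TRIB3 in Menthae Herba (0.17), HMGCS1 in Saengmaek-san (-0.04) and ALB in Soyo-san (-0.03). Against the pooled low doses they turned in Menthae Herba for FOSB (0.05), MT-ATP8 (0.05) and MT-ND1 (0.06). In Saposhnikoviae Radix they turned for HMGCS1 (-0.22), MKI67 (0.1), CREB3L3 (0.19), CDK1 (-0.01), CDT1 (0.09), MT-ATP8 (0.09), MT-ND1 (0.22) and MT-ND6 (0.22). In Saengmaek-san this held for HMGCS1 (-0.16), CREB3L3 (0.11), FABP1 (-0.07), MT-ATP8 (0.13), MT-ND1 (0.16) and MT-ND6 (0.21), and in Soyo-san for HMOX1 (0.01), ALB (-0.13) and CA9 (-0.05). The correlation of Saengmaek-san with Aucklandiae Radix was 0 over genes called in any extract. List means turned against the low dose for mitochondrially encoded genes in Menthae Herba (0.09), Saposhnikoviae Radix (0.05) and Saengmaek-san (0.28), fatty acid oxidation in Saposhnikoviae Radix (-0.03), and p53 targets (-0.02) and hypoxia genes (-0.03) in Saengmaek-san. Constituent pairs exceeded others in mean r by 0.103 to 0.251 under every alternative (0.131 to 0.152 leaving out libraries). Each exact permutation gave p = 0.083, the smallest this design can give, so the equal p-values are no sign of stability.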

Other observations

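Genes of cholesterol synthesis and uptake were lower at the high than at the low dose in all 7 tested extracts. Medians of the 24 genes were -1.49 in Polygalae Radix, -0.27 in Aucklandiae Radix, -0.87 in Menthae Herba, -0.16 in Saposhnikoviae Radix, -0.08 in Saengmaek-san, -0.55 in Guibi-tang and -0.41 in Soyo-san (camera adjusted p = 5.63e-15, 0.0437, 1.58e-52, 6.04e-22, 2.92e-07, 6.91e-25 and 4.35e-48). In that order 22, 13, 24, 7, 0, 22 and 22 members fell (22, 13, 24, 19, 3, 24 and 23 adjusted over the list alone), while 6 rose in Aucklandiae Radix, the list with adjusted p = 0.317 with an estimated correlation. These 6 included the panel gene HMGCS1, at 605 and 504 CPM at the high dose against 455 and 474 CPM at the low dose. HMGCS1 was also called higher than vehicle with Aucklandiae Radix. Against vehicle the list was not called in Aucklandiae Radix, Saposhnikoviae Radix and Saengmaek-san (medians -0.25, -0.07 and 0.04), nor in the first 2 with the GC trend removed, while in Saengmaek-san it was then called higher (camera adjusted p = 0.0286). At the low dose 9 of the 24 genes were higher than vehicle in all 7 extracts. Fatty acid synthesis genes were also lower in all 7, with medians of -1.39, -0.83, -0.58, -0.18, -0.07, -0.48 and -0.35 over 15 genes, each held with an estimated correlation, and against vehicle in all but Saengmaek-san (median -0.04, not called). NRF2 targets were higher in all but Polygalae Radix, with medians of 0.7, 0.5, 0.19, 0.21, 0.75 and 0.37, and in Aucklandiae Radix camera gave adjusted p = 0.00224 but adjusted p = 0.08 with an estimated correlation. In Saengmaek-san the median of mitochondrially encoded genes was higher than at the low dose (camera adjusted p = 6.53e-12, adjusted p = 0.0668 with an estimated correlation) with 0 of 13 members called, or 10 adjusted over the list alone. In Soyo-san, fatty acid oxidation genes were called higher against the low dose (camera adjusted p = 0.0409), with a median of -0.01 and a mean of 0.13.

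For the difference of all low doses from vehicle, the tests of graded response, sample sets, GC alone and overlapping genes were chosen after the result was seen, and the GC share of variance before. GC content and length explained a share of 0.505 of its variance over 9149 genes, so a technical GC bias of the vehicle libraries may account for much of it. By the bounds set for the test of GC alone, whether it accounts for all could not be told. A share of 0.466 of the low-dose calls, at the lowest extract, was still called once the trend was removed, and 0.529 at the highest. The numbers of genes called at the low doses also stayed within 1.5 times. These values argue against the fitted trend as the only source of the difference. A GC effect that the fit did not capture is not excluded. In Saposhnikoviae Radix and Saengmaek-san the difference did not grow with dose, as high-dose over low-dose ratios were at most 1.04 at doses 25 times apart. These were the extracts with the fewest genes between doses (141 and 74), and both parts of each ratio share the vehicle libraries. The ratio was not taken in the other extracts, so a graded response is not excluded there. Overlapping genes did not describe the difference (1.2 times as often shared among genes without overlap). Low doses of different sets differed in a share of 0.0103 as many genes as low dose and vehicle, which cannot separate vehicle's own set from treatment, and of the shared genes past 2-fold 86.7% (73.2% to 94.9%, covering counting error only) overlap another gene or are pseudogenes, against 73.2% of all tested genes.

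For CYP1A1, the sample-set test was chosen after the result was seen, and the other tests before. CYP1A1 was higher at the high than at the low dose of 7 of 7 extracts within their own sets, so a difference between sets cannot explain it. Reads shared with CYP1A2 cannot either, since the rise of CYP1A2 was at most 0.36% of that of CYP1A1. Without CYP1A1, the AHR list was still higher in 4 extracts (camera adjusted p = 1.12e-06 in Saposhnikoviae Radix, 0.00547 in Saengmaek-san, 0.000406 in Guibi-tang and 0.00132 in Soyo-san), which may reflect activation of the receptor there, although of its 7 genes only 2, 1, 5 and 3 were called higher (medians 0.23, 0.06, 0.48 and 0.32). In Menthae Herba (0.172), Polygalae Radix (0.686) and Aucklandiae Radix (0.645) it was not. The AHR and NRF2 lists share 1 gene, and NRF2 targets were also higher against the low dose in the 4 extracts with a higher AHR list. The AHR list without that gene was not tested, so the 2 responses were not separated.

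For metallothioneins, the sample-set and SLC30A1 tests were chosen after the result was seen, and the test of copies before. The list was lower at the high than at the low dose in 6 extracts, which rules out sets, and in Polygalae Radix and Aucklandiae Radix camera gave adjusted p = 0.159 and adjusted p = 0.187 with an estimated correlation. The summed CPM of 20 metallothionein genes was at least 1.5 times lower in 6 extracts (1.94 to 3.99 times), so reads moving between copies do not explain it. SLC30A1, another gene induced by zinc, fell in 3 extracts (Menthae Herba -0.82, Saengmaek-san -0.26, Soyo-san -0.33), so lower zinc-dependent transcription may fit those and cannot be told for the rest.

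For comparisons of 3 against 3 libraries, all 10 splits of the 6 libraries were tested, and the real split alone (1 of 10) gave as many called genes in each of 18 comparisons. These 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups, so any difference between the groups widens the spread and lowers the count. The splits therefore cannot tell an effect of the extract from a technical difference of the vehicle libraries. The real and the highest other counts were lowest and closest in Saengmaek-san at 500 against 20 ug/mL (86 and 2) and Saposhnikoviae Radix (330 and 2), against 4003 and 0 in Menthae Herba and 4235 and 0 in Guibi-tang.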
